A study of Mus musculus with 4 samples.

How the data were processed

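The series holds 4 libraries: 1 RNA and 1 TCR library each from sorted CD4+ CD44+ GITR- T cells of the brain and of the spleen of mice on day 60 of experimental autoimmune encephalomyelitis. The number of animals pooled per tissue is not given in the sources used here. Per the labels, cells were captured with the GEM-X 5' chemistry and 18718 brain and 38000 spleen cells were loaded. The gene expression matrices hold whole UMI counts per gene and barcode as deposited by the authors, and the TCR tables hold 1 contig per line with its read and UMI counts, V, J and CDR3 calls as deposited. Cell Ranger 9.0.0 is named in the submitters' processing notes. The notes also name GRCm39, GRCm38, mm39 and mm10 without a role, so no coordinates are given, and gene symbols and identifiers are those of the deposited tables. The sum of UMIs was 44386447 in brain and 65191435 in spleen.

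Barcodes were kept with at least 500 genes, at least 1000 UMIs and at most 10% mitochondrial UMIs, which left 4143 of 4277 brain and 8474 of 8707 spleen barcodes. Scrublet, run through scanpy 1.11.5 with an expected rate of 0.05, called 0 doublets in both libraries and so did not work here. Doublets were handled by leaving out barcodes with more than 1 productive TRB or more than 2 productive TRA chains (179 in brain, 315 in spleen), which misses doublets with 1 recovered receptor. Each library was then clustered on its own: log-normalised counts, 2000 variable genes without receptor, immunoglobulin, ribosomal, mitochondrial and haemoglobin genes, 30 principal components, 15 neighbours and Leiden clustering at resolution 0.8 (igraph 0.11.9). Clusters were named from marker lists. The thresholds for a name were set after looking at the clusters' marker values and adjusted by the names they gave: at least 3 markers higher with a mean log2 difference of 0.3, and either 2 of them among the 10 leading genes or a mean of 1.0, with a lead of 0.5 over another name. They left 22.5% of brain and 30.4% of spleen cells unnamed, including clusters of low UMI number and few receptors. A cluster of 171 B-like cells in spleen and one of 21 myeloid-like cells in brain were left out, so that 3943 brain cells (41096496 UMIs, median 9837) and 7988 spleen cells (60425529 UMIs, median 7190) entered the comparisons. A brain cluster of 101 cells led by Eomes, Gzmk, Cd8a and Cd8b1 was first left out and then kept, after its Cd4 level was seen and because its list has only 2 markers.

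Counts were summed per tissue and given as CPM. With 1 library per tissue there was no test. A gene counted as higher or lower at a ratio of at least 1.5 with an exact 95% interval (conditional binomial, Clopper-Pearson) that excludes 1, among genes of at least 10 CPM in the higher tissue. A count of 0 allows 3 counts, or 0.0730 CPM in brain and 0.0496 CPM in spleen. On simulated counts for 8352 genes of the brain against spleen comparison, this rule recovered 100 of 100 genes raised and 100 of 100 lowered by 3-fold. It called 0 of the unchanged genes. The simulated libraries came from 1 common profile and held counting error only. The simulation therefore checks the calculation and does not give the rate of false calls from variation between animals or libraries. Named genes were the 12 with the highest ratio in each direction among genes of at least 50 CPM, ranked by the interval bound nearest 1, up to 4 per gene list, the sort markers, and for expanded cells the 6 highest and 6 lowest. Receptor, immunoglobulin, mitochondrial, ribosomal, haemoglobin and sex-linked genes and unnamed gene models were left out of that ranking. Some genes that met this rule are not reported here. Genes named outside this rule serve as members of a list or were chosen after their values were seen. The gene lists (residency, recirculation, Th1, Th17, follicular helper, regulatory, cytotoxic, cytokines, inhibitory receptors, early response, chemokine receptors and integrins, survival, interferon, cell cycle, glycolysis, lipid handling, stress, transcription factors, sort markers and markers of other cells) and the marker lists for clusters were written before the data were examined. The median log2 ratio of a list was set among 10000 random lists of the same size and expression. Of the list members, 1 glycolysis gene and 3 gamma-delta genes had no matching symbol.

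Clonotypes joined cells with 1 productive TRB and at least 1 productive TRA chain by V gene and CDR3 nucleotides of both chains, using the TRA with most UMIs, which gave 2127 brain and 6245 spleen clonotypes from 7537 and 15912 contigs. Shares have exact binomial (Clopper-Pearson) 95% intervals. Equal cell numbers were taken in 100 seeded draws. Within shared clonotypes, CPM per clonotype was compared as log2(CPM + 10) over clonotypes with at least 3 cells in each tissue, and expanded cells (clonotypes of at least 5 cells) were compared with cells of clonotypes of 1 cell. Alternatives covered the scaling (TMM factors of edgeR 4.0.16, size factors of DESeq2 1.42.0, R 4.3.3), the expression minimum, the cell filters, thinning to 2000 UMIs, clustering settings and the definition of clonotypes. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9 was used.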

Results

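CD4+ T cells were isolated from the brain and the spleen of C57BL/6 mice with experimental autoimmune encephalomyelitis, an immunization-induced inflammation of the central nervous system, on day 60 after immunization. The sort took CD44+ GITR- cells, a gate for antigen-experienced conventional T cells. By their RNA, 27.1% of the spleen cells kept were naive or central memory-like and 10.9% regulatory-like, and of the brain cells 8.72% and 4.84%. From it, 18718 brain and 38000 spleen cells were loaded for droplet sequencing of RNA and of T cell receptors (TCR). Each tissue gave 1 RNA library and 1 TCR library, so there were no replicates. No test between tissues was made, and every interval covers counting error only. The RNA files held 4277 brain barcodes with 44386447 unique molecular identifiers (UMIs) and 8707 spleen barcodes with 65191435 UMIs. The median barcode held 9822 UMIs and 3126 genes in brain, and 7137 UMIs and 2616 genes in spleen. After filtering, 3943 brain cells and 7988 spleen cells remained, of which 3124 (79.2%) and 6736 (84.3%) had a paired receptor. The design addresses how CD4+ CD44+ T cells in the chronically inflamed brain differ from those in the spleen, and how their clones are spread over both tissues.

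Brain T cells differed from spleen T cells most in inflammatory cytokines and in immediate-early genes. Il17a (ENSMUSG00000025929), the signature cytokine of Th17 cells, stood at 238 CPM (UMI counts scaled to a common total) in brain and 0.596 CPM in spleen, a ratio of 399 (95% interval 288 to 570). The chemokine genes Ccl1 and Ccl4 were 145-fold (106 to 204) and 50.4-fold (40.5 to 63.6) higher in brain. In spleen, the genes with the highest levels relative to brain belonged to lymphoid recirculation and quiescence. The costimulatory receptor gene Cd27 stood at 262 CPM in spleen and 72.2 CPM in brain. Among 8637 genes with at least 10 CPM in either tissue, 847 were at least 1.5-fold higher in brain, 746 were at least 1.5-fold higher in spleen and 7044 were neither. The median log2 ratio of all measured genes was -0.09. Of the 12 genes leading in brain, Atf3 (366-fold, 225 to 640), Fosb (42.8-fold), Fos (22.4-fold), Klf4 (34.8-fold), Nr4a2 (18.1-fold) and Nr4a3 (18.0-fold) encode transcription factors induced by stimulation or stress. The remaining brain-leading genes were Cdkn1a (39.7-fold), a cell cycle inhibitor, Krt83 (23.9-fold) and Lilrb4b (17.0-fold), whose counts can be shared with a near-identical copy. The other spleen-leading genes, with brain to spleen ratios from 0.155 to 0.310, were Slc28a2b, which also has a near-identical copy, the Notch pathway gene Dtx1 (22.6 CPM in brain, 114 CPM in spleen), Dapl1, Igfbp4, Nsg2, Actn1, Als2cl, Izumo1r, Ddit4 and Ephx1. The sort markers did not separate the tissues for Cd4 (ratio 0.992, 0.971 to 1.01) and differed for Cd44, which was 1.96-fold higher in brain (1.90 to 2.02). Tnfrsf18, which encodes GITR, had a ratio of 1.19.

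Genes known to be higher in tissue-resident memory T cells were higher in brain, and genes of recirculating cells were higher in spleen. Of 22 measured residency genes, 20 were higher in brain, 0 were higher in spleen and 2 (P2rx7 and Inpp4b) were neither. The median log2 ratio was 1.53, above all of 10000 random lists of matched expression. The transcriptional regulator gene Bhlhe40 was 15.6-fold higher (733 against 46.9 CPM), the G protein regulator genes Rgs2 and Rgs1 15.2-fold and 10.4-fold. Cd69, whose product retains T cells in tissue, was 4.66-fold higher, and the chemokine receptor gene Cxcr6 1.97-fold. Of 17 recirculation genes, 12 were higher in spleen, 2 higher in brain and 3 neither. The median log2 ratio was -0.96, below all of the random lists. Ccr7, the lymph node homing chemokine receptor gene, stood at 119 CPM in brain and 324 CPM in spleen. Lef1 stood at 217 and 554 CPM, and S1pr1, which encodes the receptor for tissue egress, at 134 and 261 CPM. Klf2, which activates S1pr1, had a ratio of 0.975. Ly6c2 was 2.55-fold higher in brain, though its counts can be shared with the near-identical Ly6c1. The residency list holds 3 genes of the early-response list (Cd69, Nr4a1 and Nr4a2) and 1 of the glycolysis list (Hilpda). The heat shock and dissociation stress list was higher in the same brain library, with 15 of 17 genes up and a median log2 ratio of 1.85. Among 20 chemokine receptors and integrins, 8 were higher in brain, 5 in spleen and 7 neither (median log2 0.13, percentile 97.1). Ccr8 stood at 85.4 CPM in brain and 7.75 CPM in spleen, Itga1 was 4.68-fold higher in brain, and Cxcr5 and Ccr9 had ratios of 0.211 and 0.202. Of 23 transcription factors of memory and effector T cells, 9 were higher in brain, 6 in spleen and 8 neither (median log2 0.25, percentile 99.9). Klf6 was 6.87-fold and Rbpj 3.54-fold higher in brain, while Id3, a regulator of long-lived memory cells, had a ratio of 0.257.

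Th17 and Th1 genes were higher in brain, while follicular helper genes were split, with a median towards spleen. All 11 measured Th17 genes were higher in brain (median log2 2.31, percentile 100), among them Il22 (72.7-fold), Il17f (60.6-fold) and the interleukin 1 receptor gene Il1r1 (11.5-fold). Of 13 Th1 genes, 10 were higher in brain, 0 in spleen and 3 neither (median log2 1.23, percentile 100). Ifng, the Th1 signature cytokine, stood at 315 CPM in brain and 21.2 CPM in spleen, a ratio of 14.9 (14.1 to 15.8). Ccl3 had a ratio of 121 (60.9 to 281) from 8 spleen UMIs, and Il18r1 was 2.66-fold higher. Of 11 effector cytokine genes, 8 were higher in brain, 1 (Il4) in spleen and 2 neither (median log2 2.29, percentile 100). Csf2, which encodes a cytokine required for the experimental disease, was 8.61-fold higher in brain. Of 11 follicular helper genes, 5 were higher in spleen, 3 in brain and 3 neither (median log2 -0.58, percentile 0). Cxcr5 and Slamf6 had brain to spleen ratios of 0.211 and 0.340, whereas Rgs16 and Icos were 8.41-fold and 2.74-fold higher in brain. Within cell classes from clustering the follicular helper list did not keep 1 direction. In Th17-like cells 6 of 10 of its genes were higher in brain and 3 in spleen (median log2 1.34), in interferon-response-like cells 5 of 9 and 1 (0.62), and in Th1-like cells 3 of 10 and 5 (-0.52). Of 11 cytotoxic effector genes, 6 were higher in brain, 1 (Prf1) in spleen and 4 neither (median log2 0.88, percentile 100). Gzma was 3.87-fold, Ctsw 3.28-fold and Fasl 2.93-fold higher in brain. Gzmk was 4.60-fold higher (log2 2.20), and at log2 1.49 without a brain cluster of 101 cells led by Eomes and Gzmk. The 8 regulatory T cell genes were split, with 3 higher in brain, 3 in spleen and 2 neither (median log2 0.31, percentile 97.6). Ctla4 and Capg were 2.78-fold and 2.17-fold higher in brain, Izumo1r and Ikzf2 had ratios of 0.288 and 0.475. Of 10 inhibitory receptor genes, 5 were higher in brain, 3 in spleen and 2 neither (median log2 0.45, percentile 99.8). Havcr2 was 23.7-fold higher in brain, and Cd160 and Cd200 had ratios of 0.217 and 0.419.

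Genes of recent activation and of cell stress were higher in brain as well. Of 11 early-response genes of TCR signalling, 9 were higher in brain, 0 in spleen and 2 neither (median log2 2.22, percentile 100), with Egr1 13.0-fold and Nr4a1 6.73-fold higher. Of 17 heat shock and dissociation stress genes, 15 were higher in brain, 0 in spleen and 2 (Dnaja1 and Hspa8) neither (percentile 100), including Jun (10.1-fold) and Dusp1 (10.8-fold). The median cell carried 15315 CPM of stress-list genes in brain and 3713 CPM in spleen, and 83.0% of brain cells lay above the 95th percentile of spleen cells. Of 11 measured glycolysis and hypoxia genes, 6 were higher in brain, 0 in spleen and 5 neither (median log2 0.72, percentile 99.9). They were led by the hexokinase gene Hk2 (13.6-fold), Hif1a (3.71-fold), Hilpda (2.67-fold) and Pfkp (2.14-fold). Of 15 interferon response genes, 6 were higher in brain, 0 in spleen and 9 neither (median log2 0.49, percentile 99.99). Ifit3b was 2.90-fold, Ifit3, its near-identical copy, 2.62-fold, Mx1 2.56-fold and Rsad2 2.45-fold higher. Of 8 survival genes and cytokine receptors, 3 were higher in brain, 0 in spleen and 5 neither (median log2 0.41, percentile 98.7). Bcl2a1b, which has near-identical copies, was 2.57-fold, Bcl2 1.74-fold and Il2rb 1.64-fold higher, and Mcl1 at a ratio of 1.36. Of 12 cell cycle genes, 5 were higher in spleen, 0 in brain and 7 neither (median log2 -0.39, percentile 1.6). Ube2c and Birc5 had brain to spleen ratios of 0.250 and 0.389. Of 7 lipid handling genes, 2 (Fabp5, 1.55-fold, and Plin2, 1.63-fold) were higher in brain, 0 in spleen and 5 neither (median log2 -0.03, percentile 76.2). Of the 5 sort markers, Cd44 was higher in brain and 4 were neither (median log2 -0.01, percentile 54.4). Among markers of other cells, no astrocyte, neuron or erythroid gene reached 10 CPM. Measured ones were the B cell gene Ighm (ratio 0.347), the myeloid gene Cst3 (1.33), the microglia genes Cx3cr1 (2.14) and Gpr34 (1.59), the oligodendrocyte genes Cnp (0.664) and Mbp (1.16), the endothelial genes Ly6c1 (0.374) and Pecam1 (0.616), and Klrb1b (7.47) and Cd8b1 (1.42) of the list for CD8 T, NK and gamma-delta T cells. Cx3cr1 was also a leading gene of clusters kept in the comparisons, of 33 cells in brain and 91 in spleen. Without the cluster led by Eomes and Gzmk, Cd8b1 turned from log2 0.51 to -0.47.

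**Figure D1:**
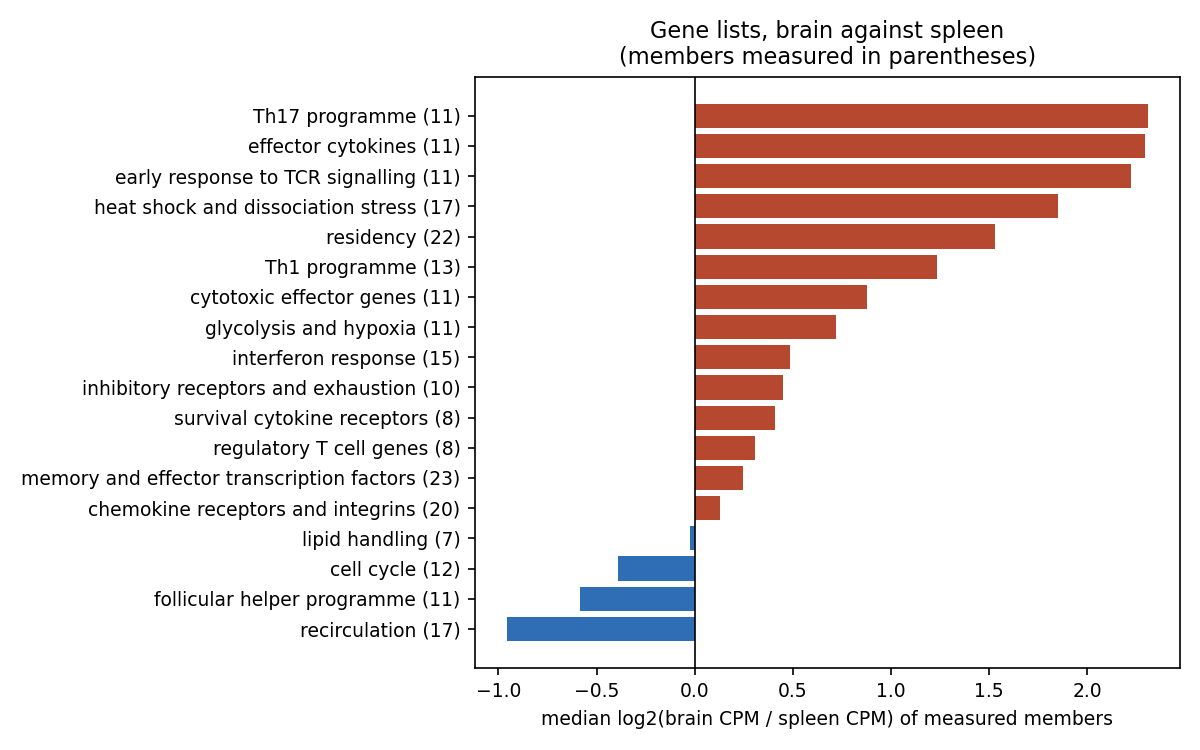
Median log2 ratio of brain to spleen CPM (x axis) over the measured members of each gene list (y axis, members measured in parentheses), 1 bar per list, red for medians above 0 and blue for medians below 0. The Th17 programme (2.31) and effector cytokines (2.29) stand highest, and the recirculation list (-0.96) lowest.

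Clustered on its own, each tissue separated into effector, regulatory, innate-like and naive-like groups of cells. In brain, Th17-like cells in 3 clusters made up 24.1% of cells (22.8 to 25.5), cytotoxic-like cells 12.2%, resident-memory-like cells 10.9% (9.90 to 11.9), and naive or central memory-like cells 8.72%. Th1-like cells were 7.03%, regulatory-like cells 4.84%, interferon-response-like cells 4.31%, NKT-like cells 3.83%, proliferating-like cells 1.01% and Th2-like cells 0.533%. A further 22.5% were in clusters without a name. Of the 481 cytotoxic-like brain cells, 347 were in 1 cluster led by Rgs16, Ccl4, Klrc1 and Klrd1. That cluster had 4 markers of its list higher, at a mean log2 difference of 0.46. No granzyme or perforin gene was among its 10 leading genes, so the name does not by itself show cytotoxic cells. In spleen, naive or central memory-like cells in 3 clusters made up 27.1% (26.2 to 28.1), regulatory-like cells 10.9%, and NKT-like cells 9.19%. Th1-like cells were 6.37%, Th17-like cells 5.68%, follicular helper-like cells 5.11%, interferon-response-like cells 3.36%, proliferating-like cells 1.48% and cytotoxic-like cells 0.413% (33 cells), with 30.4% unnamed. An unnamed spleen cluster of 91 cells was led by Gzma, Zeb2, S1pr5, Cx3cr1 and Klrg1, as was a brain cluster of 33 cells named cytotoxic-like, so the spleen share of such cells depends on the naming rule. The Th17-like share depended on the clustering settings. It was 14.8% in brain at a Leiden resolution of 1.2, and in spleen 11.3% at 0.5 and 3.51% with another random seed. Sizes of classes are not compared between tissues, because the genes that define them differed between the tissues, and the CD44+ GITR- sort limits the naive-like and regulatory-like shares. Of the NKT-like cells with a paired receptor, 81.7% in brain and 92.0% in spleen carried the invariant TRAV11-TRAJ18 alpha chain of NKT cells.

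The residency list had a median above 0 within each named class compared between the tissues, as had the stress list. Classes were named per tissue from markers that include Il17a and Ifng, so the comparison of these 2 genes within Th17-like and Th1-like cells, respectively, partly follows from the naming. Between the Th17-like cells of brain (952 cells in 3 clusters) and spleen (454 cells in 1 cluster), 18 of 21 residency genes were higher in brain and 0 in spleen (median log2 2.04). There, 13 of 17 recirculation genes were higher in spleen and 2 in brain (median log2 -1.70). Ccr6 had a ratio of 0.421. Il17a stood at 779 CPM in brain and 2.22 CPM in spleen, a ratio of 351 (178 to 813) from 8 spleen UMIs. Over the Th17 list, 6 of 11 genes were higher in brain and 1 in spleen (median log2 0.61). Ifng (45.1-fold, 27.3 to 80.8) and Csf2 (12.8-fold, 8.04 to 21.7) were also higher in Th17-like brain cells. Of the Th1 list there, 8 of 11 genes were higher in brain and 0 in spleen (median log2 2.32). The Th17-like cells are therefore not matched in helper type. Between the Th1-like cells (277 in brain and 509 in spleen, 1 cluster each), 15 of 22 residency genes were higher in brain and 1 in spleen (median log2 1.48). There, 12 of 17 recirculation genes were higher in spleen and 2 in brain (median log2 -1.35). Tbx21, which encodes the Th1 lineage transcription factor, had a ratio of 0.976 (0.855 to 1.11) in Th1-like cells. Of the Th1 list, 3 of 11 genes were higher in brain and 0 in spleen (median log2 0.02). Ifng was 7.76-fold higher (6.99 to 8.64), and it is among the 10 leading genes of the brain cluster and not of the spleen cluster. Of the Th17 list, 0 of 6 genes were higher in brain and 5 in spleen in Th1-like cells (median log2 -2.12). These cells are not matched in helper type either. Of the residency genes, 14 of 20 were higher in brain and 0 in spleen in regulatory-like cells (191 and 870 cells, 1 cluster each, median log2 1.17). In NKT-like cells (151 cells in 1 cluster and 734 in 2), 13 of 22 were higher and 4 lower (median log2 0.88), and Cxcr6 had a ratio of 0.444. In interferon-response-like cells (170 in 1 cluster and 268 in 2), 20 of 22 were higher and 0 lower (median log2 2.45). That class, too, is not matched in helper type. There 8 of 8 Th17 genes (3.67), 13 of 13 Th1 genes (1.80) and 8 of 8 cytokine genes (2.24) were also higher in brain. Of its recirculation genes, 11 of 17 were higher in spleen (-0.94). In regulatory-like and NKT-like cells the recirculation shift was smaller: 4 of 16 genes were higher in spleen and 2 in brain (-0.26), and 5 of 17 and 2 (-0.17). Stress genes higher in brain were 15 of 17 in Th17-like cells (median log2 2.45), 15 of 18 in Th1-like cells (1.98) and 14 of 17 in regulatory-like cells (1.38). They were 15 of 18 in NKT-like cells (2.35) and 14 of 17 in interferon-response-like cells (1.94). The stress median was above the residency median in Th17-like, Th1-like, regulatory-like and NKT-like cells. It was below the residency median in interferon-response-like cells.

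Naive or central memory-like cells (344 in 1 brain cluster, 2167 in 3 spleen clusters) also had higher residency and early-response genes in brain. Of 12 residency genes measured in them, 9 were higher in brain and 0 in spleen (median log2 1.37), of 10 early-response genes 7 and 0 (median log2 1.92), and of 16 stress genes 14 and 0 (median log2 1.33). Of 17 recirculation genes, 3 were higher in brain and 0 in spleen here (median log2 0.09). Klf2 stood at 2483 CPM in brain and 749 CPM in spleen (3.31-fold, 3.22 to 3.41). Genes chosen here after their values were seen were Nr4a2 (52.3-fold), Nr4a3 (45.8-fold), Maff (20.2-fold), Dusp5 (16.4-fold), Nr4a1 (14.7-fold), Fos (10.3-fold), Dusp1 (9.53-fold), Junb (9.19-fold) and Cd69 (2.66-fold), all higher in brain. The stress response gene Ddit4 was lower in brain, with a ratio of 0.221. Of 492 genes higher in the remaining brain cells among 7859 measured in both, 349 (70.9%) were also higher in naive-like brain cells, where independent lists would share 38.3.

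**Figure D2:**
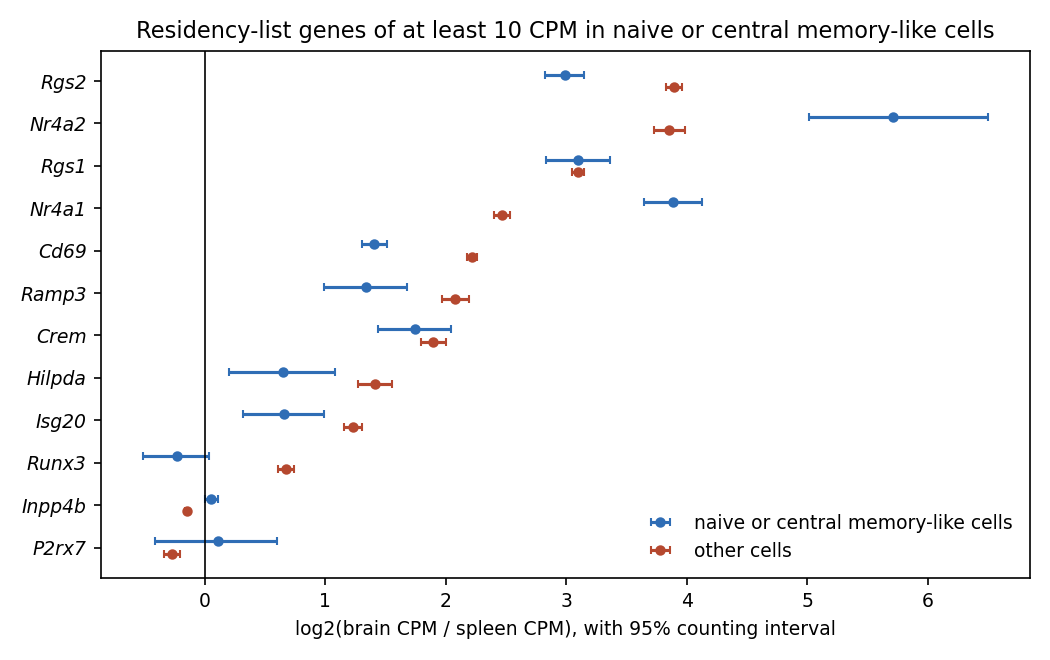
Log2 ratio of brain to spleen CPM (x axis) of the 12 residency genes of at least 10 CPM in naive or central memory-like cells (y axis), in those cells (blue) and in all other cells (red), points with 95% counting intervals. In naive-like cells 9 of the 12 genes were at least 1.5-fold higher in brain.

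In these libraries, a far larger share of brain than of spleen T cells belonged to expanded clonotypes. In brain, 41.2% of cells with a paired receptor (1288 of 3124, exact binomial 95% interval 39.5 to 43.0) belonged to a clonotype of at least 2 cells, against 11.1% in spleen (748 of 6736, 10.4 to 11.9). At equal cell numbers the spleen share was 7.50% ± 0.557 (SD over 100 draws). These draws do not account for cell class or for the number of animals pooled per tissue, which is not known and can affect such shares. The shares within classes below were not drawn to equal cell numbers. Clonotypes of at least 5 cells held 23.1% of brain and 3.18% of spleen cells, those of at least 10 cells 13.8% and 1.26%, and the 10 largest clonotypes 10.5% and 2.12%. Within brain, cells of clonotypes of at least 2 cells made up 79.4% of Th1-like, 72.5% of cytotoxic-like, 56.8% of Th17-like and 51.8% of resident-memory-like cells, but 1.28% of naive-like and 3.21% of regulatory-like cells. Within spleen, they made up 44.6% of follicular helper-like, 42.0% of Th1-like, 23.4% of Th17-like and 1.55% of naive-like cells. The largest brain clonotype (TRBV13-3 with TRAV13N-1) had 67 brain cells, 51 of them Th1-like, and 0 of 6736 spleen cells. With 0 taken to allow 3 counts, its spleen share could be up to 0.0445%. The largest spleen clonotype (TRBV26 with CDR3 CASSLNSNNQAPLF and TRAV7-5 with CDR3 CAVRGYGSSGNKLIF) had 60 spleen and 57 brain cells. The third in brain, TRBV20 with TRAV7D-2, had 48 brain cells and 1 spleen cell. The next in spleen were a TRBV26 and TRAV7-5 clonotype with beta CDR3 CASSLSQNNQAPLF (15 spleen and 8 brain cells) and a TRBV2 and TRAV14N-1 clonotype. The latter had 10 spleen cells, 9 of them follicular helper-like, and 0 of 3124 brain cells (up to 0.0960% at 3 counts).

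**Figure D3:**
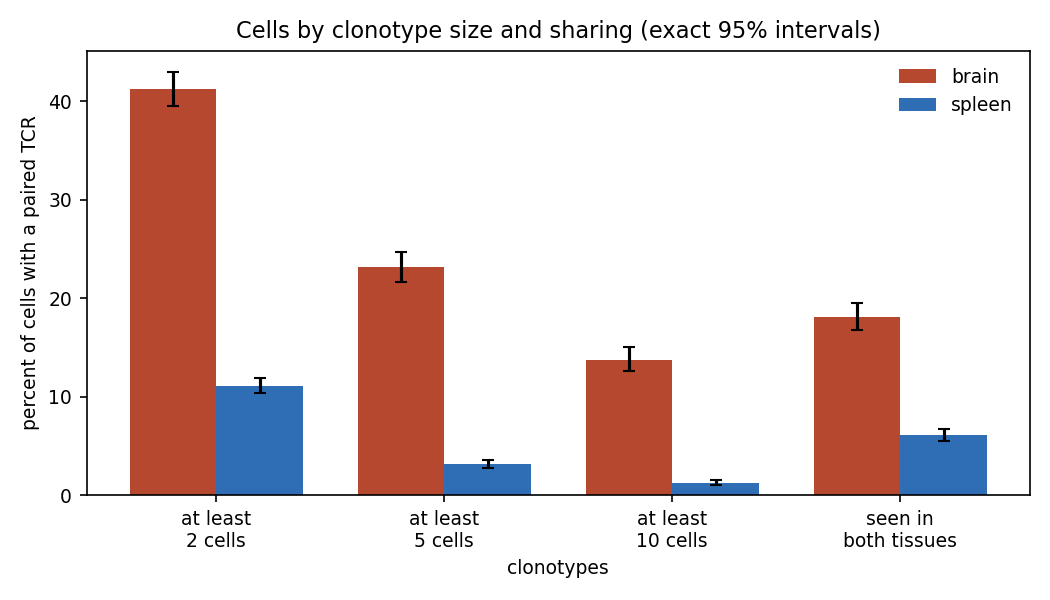
Percent of cells with a paired receptor (y axis) in clonotypes of at least 2, 5 and 10 cells and in clonotypes seen in both tissues (x axis), in brain (red) and spleen (blue), with exact 95% intervals. Brain bars exceed spleen bars in each group, at 41.2% against 11.1% for at least 2 cells.

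Part of the brain repertoire was also found in the spleen, and the share seen there rose with the number of brain cells per clonotype. The tissues shared 187 nucleotide-identical clonotypes, which held 18.1% of brain cells (567 cells, 16.8 to 19.5) and 6.09% of spleen cells (410 cells, 5.53 to 6.68). They made up 8.79% of brain and 2.99% of spleen clonotypes. With spleen sampled down to the number of brain cells, shared clonotypes held 12.1% of brain cells. Of brain clonotypes with 1 cell, 5.83% (107 of 1836) were seen in spleen. The share was 25.1% (57 of 227) of those with 2 to 4 cells, 30.4% (14 of 46) of those with 5 to 9 cells and 50% (9 of 18, 26.0 to 74.0) of those with at least 10 cells. A more frequent clone is also more likely to be sampled in both tissues. Whether the rise exceeds what sampling gives was not tested. Of the shared cells, 34.2% in brain were Th17-like, 19.4% cytotoxic-like and 16.9% Th1-like. In spleen 36.6% were Th1-like, 17.3% Th17-like and 12.2% follicular helper-like. The third largest shared clonotype (TRBV26 with TRAV9-1) had 28 brain and 3 spleen cells. V gene use differed most for TRAV11, the alpha gene of invariant NKT cells, with 5.55% of brain and 10.5% of spleen clonotypes. Cells with the invariant TRAV11-TRAJ18 chain were 3.81% (3.17 to 4.54) of brain and 9.63% (8.94 to 10.4) of spleen cells. The joint label TRBV12-2+TRBV13-2 was used by 11.3% of brain and 12.9% of spleen cells. Without NKT-like cells and invariant receptors the direction for this label turned, to 9.59% (8.56 to 10.7) of brain and 8.99% (8.28 to 9.74) of spleen cells. Per clonotype it was then 10.3% and 9.11%. The single label TRBV12-2 was used by a further 0.768% of brain and 0.549% of spleen cells, and TRBV13-2 by 1.66% and 2.08%. TRBV5 was used by 9.67% and 8.39%, and TRBV3 by 7.71% and 7.93%. TRBV20 was used by 8.58% and 4.45%, TRBV13-3 by 5.31% and 5.98%, and TRAV7D-2 by 6.37% and 3.56%. Counted per clonotype, TRBV20 was used by 5.92% (4.96 to 7.01) in brain and 4.29% (3.80 to 4.82) in spleen, TRBV13-3 by 4.09% and 6.20%, TRBV5 by 9.78% and 8.42%, and TRAV7D-2 by 4.89% and 3.54%. The alpha genes TRAV3-3, TRAV6N-7 and TRAV6D-6 were used by 1.98%, 3.55% and 2.14% of brain cells and by 1.19%, 2.36% and 2.97% of spleen cells.

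Cells of the same clone differed between brain and spleen in residency and stress genes, while the Th1 and Th17 lists had medians near 0, which changed sign with the number of cells required. In the 17 clonotypes with at least 3 cells in each tissue (170 brain and 150 spleen cells, clonotypes weighted equally), the residency list had a median log2 difference of 1.11, against 1.21 over all cells. It was above 0 in 16 clonotypes and below 0 in 0. The 9 residency genes also higher in naive-like brain cells had a median of 2.67, against 2.15 over all cells. For the other 13 the median was 0.32, against 0.76 over all cells. This split was made after values were seen. Rgs1 (mean log2 difference 3.75 ± 2.05, SD over clonotypes), Cd69 (2.67 ± 1.69) and Bhlhe40 (2.67 ± 1.30) were higher in brain in 17 of 17 clonotypes, as were the inhibitory receptor gene Ctla4, Hif1a and Dusp1. Cxcr6 was higher in 7 and lower in 9 clonotypes (0.32 ± 1.27), and Runx3 higher in 5 and lower in 11. The recirculation list had a median of -0.72 against -0.91 over all cells, with 13 clonotypes below and 1 above 0. S1pr1 (-1.14 ± 1.86) was lower in 13 and Klf2 (-1.53 ± 2.27) in 12 clonotypes. The Th1 list (-0.05 against 1.09) and the Th17 list (-0.03 against 1.51) were near 0, where 5 of the 11 Th17 genes and 2 of the 13 Th1 genes were at a difference of 0 in most clonotypes. The Th1 median was -0.34 in the 4 clonotypes with at least 5 cells in each tissue and 0.34 in all 187 shared clonotypes, and the Th17 median -0.27 and 0.12. Ifng was higher in brain in 13 and lower in 1 of the clonotypes (1.53 ± 1.68), Il17a higher in 6 and lower in 1 (1.49 ± 2.70), Tbx21 higher in 5 and lower in 12, and Itga1 higher in 11 and lower in 1. Stress genes were higher in brain in 17 of 17 clonotypes by their median (1.70 against 1.80 over all cells), and early-response genes in 14 (1.66 against 1.73). Medians were 0.40 against 1.17 for cytokines, 0.12 against 0.85 for cytotoxic genes, 0.44 against 0.70 for glycolysis genes and 0.33 against -0.32 for follicular helper genes. With any 1 clonotype left out, the residency median ran from 0.99 to 1.29. With CPM + 50 in place of CPM + 10 the medians were smaller, at 0.61 against 0.82 over all cells for residency, -0.45 against -0.75 for recirculation and 1.06 against 1.63 for stress genes.

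**Figure D4:**
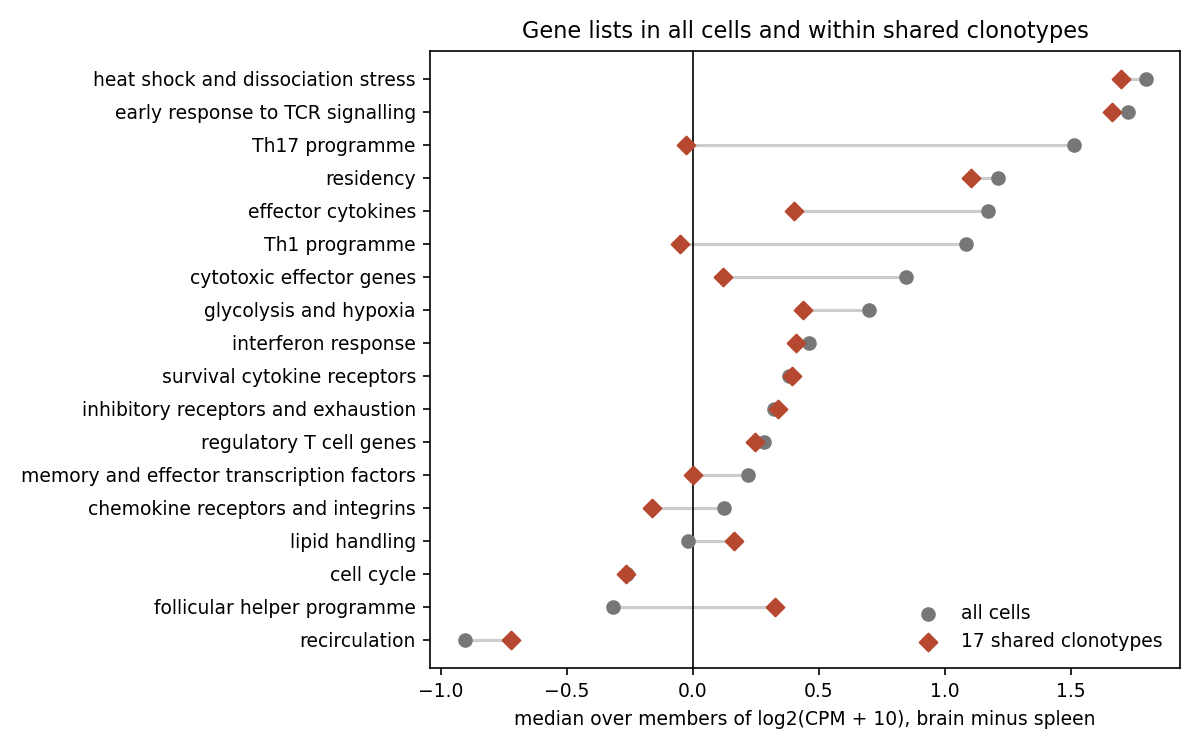
Median over list members of the difference in log2(CPM + 10), brain minus spleen (x axis), for each gene list (y axis), in all cells (grey circles) and within the 17 shared clonotypes (red diamonds). The residency list is at 1.21 and 1.11, the Th17 programme at 1.51 and -0.03.

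Within each tissue, cells of expanded clones had more effector gene expression than cells of clonotypes seen in 1 cell only, and lower Ccr7, Dapl1 and Igfbp4, genes of naive and recirculating cells. Expanded cells here are those of clonotypes of at least 5 cells. The groups were not matched for cell class. Of naive-like cells with a paired receptor, 1.28% in brain and 1.55% in spleen were in clonotypes of at least 2 cells. Differences in cell class and in expansion therefore cannot be told apart here. Of the 214 expanded spleen cells, 60 were of 1 clonotype, 40 of them Th1-like. In brain (723 against 1836 cells), 438 genes were higher and 296 lower in expanded cells. In spleen (214 against 5988 cells), 1196 were higher and 503 lower. Of 8158 genes measured in both tissues, 352 were higher in expanded brain cells and 994 in expanded spleen cells, and 277 in both. Another 164 were lower in both. In brain, 9 of 11 Th17 genes were higher and 1 lower (median log2 0.96), and 8 of 12 Th1 genes were higher and 1 lower (0.91). Of 22 residency genes 9 were higher, 1 lower and 12 neither (0.42). Of the recirculation genes, 13 of 17 were lower and 0 higher (-1.16), and 2 of 15 interferon genes were lower and 0 higher (-0.29). Of the markers of other cells, 1 of 3 microglia genes and 1 of 2 genes of the CD8 T, NK and gamma-delta list were higher. The 1 measured B cell gene and 1 of 2 endothelial genes were lower. In spleen, 11 of 11 Th1 genes (1.82), 8 of 8 Th17 genes (1.70), and 10 of 12 follicular helper genes (1.85, with 0 lower) were higher. Of 22 residency genes there 10 were higher, 3 lower and 9 neither (0.38). Of the interferon genes, 8 of 13 were lower and 1 higher (-0.66), and of the recirculation genes 6 of 18 were lower and 4 higher (-0.21). Ifng was 3.50-fold higher in expanded brain cells (3.35 to 3.66), with UMIs in 62 of 64 clonotypes, Rgs16 3.60-fold, Nrgn 6.85-fold and Igfbp7 5.92-fold. Single clonotypes carried Spp1 (86.0-fold, 49.7 to 163, with 97.7% of UMIs from 1 clonotype) and much of Penk (13.9-fold, 57.6%). Lower in expanded brain cells were Ccr7 (29.8-fold), Actn1 (14.7-fold), Nsg2 (8.87-fold), Igfbp4 (6 UMIs) and Dapl1 (1 UMI, expanded to single ratio 0.00231, 5.84e-05 to 0.0129). In spleen, Sostdc1 (32.2-fold), Spp1 (31.2-fold, 63.9% from 1 clonotype), Lilrb4b (18.9-fold, 58.6%) and Zeb2 (16.5-fold, 65.8%) were higher, and the 532 Jchain UMIs all came from 1 cell. Markers of other cells were also higher there. Igkc (51.2-fold) and Ighm (1.81-fold) had 183 of 200 and 653 of 840 UMIs in that same cell, without which they were at ratios of 4.39 and 0.407. The myeloid gene Cst3 was 1.72-fold higher. Cx3cr1, of the microglia list, was 20.1-fold higher, with 55.4% of UMIs from 1 clonotype. Cx3cr1 was also a leading gene, with Gzma, Zeb2, S1pr5 and Klrg1, of the unnamed spleen cluster of 91 kept cells. Its level therefore does not by itself mark other cells. Without that cell, 11 of 11 Th1, 8 of 8 Th17 and 10 of 12 follicular helper genes were still higher. Lower in expanded spleen cells were Igfbp4 (0 UMIs, at least 88.4-fold by the exact interval), Dapl1 (31.7-fold), Actn1 (14.3-fold), Ccr7 (13.0-fold) and St8sia6 (3 UMIs, ratio 0.0335, 0.00690 to 0.0979).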

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

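The tests of Foxp3 against free RNA, of residency genes in naive-like cells, of the residency genes under 10 CPM there by stress level, and of clones for the residency genes not higher in naive-like cells were chosen only after the result was seen.

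Between tissues, 29 genes were at least 1.5-fold higher in expanded cells (clonotypes of at least 5 cells) of 1 tissue and lower in those of the other, and this difference was not tested. Of these, 12 are T cell receptor segments, whose level follows from which clonotypes expanded, 1 is Ighm, with 653 of 840 UMIs in 1 expanded spleen cell, and 16 are other genes. The largest among genes that are not T cell receptor segments was Ikzf2, a transcription factor gene of regulatory T cells, with an expanded to single ratio of 0.154 (0.126 to 0.185) in brain and 1.85 (1.68 to 2.02) in spleen, followed by Gpm6b (0.537 and 4.64), Gzmb (0.545 and 3.13) and Ly6c2 (0.637 and 3.54). The spleen library held 171 B-like cells (2.10% of clustered cells) outside the comparisons, with Cd79a at 3176 CPM against 0.960 CPM in the kept cells and Cd3e at 54.0 against 742 CPM. The brain library held 21 myeloid-like cells (0.530%) with C1qa at 690 CPM against 0.998 CPM and Cd3e at 682 against 738 CPM, and 15 of the 21 carried a TRB chain. The 21 cells had a median of 12595 UMIs. Whether these cells are doublets was not tested.

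The higher residency genes in brain, 20 of 22, could reflect the cells' residence in tissue or a response to isolating them from brain. Over the whole list, different clones in the 2 tissues are argued against, since within shared clonotypes the median was 0.911 of that in all cells, and 0.741 with CPM + 50. For the 12 genes measured in naive-like cells the dissociation response stays open and has the values it needs, since those cells, which are not expected to be resident, showed 0.691 of the difference in the other cells. A response that scales with each cell's stress level was left undecided. The ratio between the 900 brain cells with the lowest and the 900 with the highest stress share was 0.700 for 19 genes. It was 0.749 for the 10 genes under 10 CPM in naive-like cells, just under the bound of 0.75 set for this test. A higher value could not have argued against a response in most brain cells, because the cells with the lowest stress share may have responded too. Their stress share ran up to 10147 CPM, against a median of 3787 CPM in spleen cells that were not naive-like. Of all brain cells, 83.0% lay above the 95th percentile of spleen cells. For the 13 genes not higher in naive-like cells, different clones also stay open at 0.419, and the outcome turns on a split made after values were seen, since the 10 genes under 10 CPM gave 0.595, so residence in tissue remains a hypothesis for these data.

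The 187 clonotypes found in both tissues may mark clones that seeded brain and spleen, a hypothesis. Carry-over of barcodes between the libraries is argued against, since 0 of 567 brain cells with a shared clonotype had a barcode carrying it in spleen. Independent generation of the same receptor is argued against as the main source, since 12 amino acid pairs were shared with different nucleotides only, 0.0652 of the 184 shared with identical ones. Blood left in the brain vessels and the number of pooled animals were not tested.

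Foxp3, the regulatory T cell transcription factor gene, was found in cells sorted as GITR-negative: 205 brain and 723 spleen cells had at least 2 UMIs. Free RNA is argued against, since Lrrc32, another regulatory T cell gene, was 37.0-fold higher in brain and 31.4-fold higher in spleen in those cells than in cells with 0 Foxp3 UMIs. In brain, any Foxp3 UMI was found in 1 of the 21 myeloid-like cells, against 6.77% of kept cells. These are too few cells to compare, and 15 of the 21 carried a TRB chain. In spleen, any Foxp3 UMI was found in 3 of the 171 B-like cells, against 11.9% of kept cells. Tnfrsf18, which encodes GITR, stood at 430 CPM in regulatory-like brain cells against 157 CPM in the rest, and at 343 against 120 CPM in spleen, so the cells may be regulatory cells of low surface GITR or sort carry-over, which these data do not separate.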

How the results depend on the processing

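The settings without NKT-like cells, regulatory-like cells, naive-like cells, the cluster led by Eomes and Cd8a, clusters with few receptors, and the highest 5% of Scrublet scores were chosen after seeing the data, and the others were fixed beforehand. Of 1504 values of 94 named genes under 16 settings (11 of them fixed beforehand), 1106 stayed within their counting interval, 398 moved beyond it and 0 of these genes' calls turned. The uncalled Cd8b1 changed sign without the cluster led by Eomes and Cd8a, as did the values near 0 of Cd4 and Cd3e in some settings. Without a minimum CPM, 2606 genes were higher in brain and 2289 in spleen, and with 50 CPM 450 and 221, with 5 Th17 genes higher in brain, because fewer genes pass a higher minimum. Calls higher in brain were 53.2% of all calls, 59.1% with TMM and 60.0% with DESeq2 factors, which kept 847 of the 847 brain calls and 643 and 630 of the 746 spleen calls, and 43.7% without naive-like cells. Over all genes 1 call turned, without regulatory-like and NKT-like cells. Keeping Scrublet calls changed nothing, as there were none, and thinning left out 85 brain and 258 spleen cells. Class shares depended on clustering, and the cause was not tested: Th17-like cells in brain were 14.8% at resolution 1.2 and 20.7% with 1000 variable genes, in spleen 11.3% at 0.5, 3.59% at 1.2 and 3.51% with another seed. Naive-like cells were 12.5% and 9.76% in brain at resolution 1.2 and with 1000 genes, and 20.6%, 22.4% and 20.9% in spleen at 1.2, with 1000 genes and with another seed. Regulatory-like cells were 5.65% in brain at 0.5, 5.62% with 1000 genes, and 12.3% in spleen at 1.2. Shares of cells in clonotypes of at least 2 cells were 43.0% in brain and 12.6% in spleen by TRB alone, 23.1% and 3.18% for clonotypes of at least 5 cells, and for at least 2 cells in spleen 7.50% at equal cell numbers and 12.2% without NKT-like cells. Shared brain cells were 20.3% by TRB alone, 19.7% by amino acids and 12.1% at equal numbers. Within shared clonotypes the Th1 median was -0.34 for at least 5 cells in each tissue (4 clonotypes) and 0.34 for at least 1 (187 clonotypes), against -0.05, and the Th17 median -0.27 and 0.12, against -0.03, and 0.02 with CPM + 50 and 0.09 by TRB alone. The cause was not tested. With CPM + 50 the residency median within shared clonotypes was 0.61, against 1.11 with CPM + 10. Genes lower in expanded spleen cells were 307 with clonotypes of at least 2 cells counted as expanded, against 503. Without the 1 expanded spleen cell that held the Jchain UMIs, a setting chosen after seeing the data, 1212 genes were higher and 498 lower, against 1196 and 503. No paired analysis was possible because each tissue gave 1 library, so animals or libraries could not be paired, and only clonotypes were compared in pairs.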

Other observations

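The cluster of 101 brain cells led by Eomes, Gzmk, Cd8a and Cd8b1 was described after its values were seen. It had Cd4 at 320 CPM against 339 CPM in the remaining brain cells, Cd8a at 313 against 2.56 CPM, Cd8b1 at 486 against 10.3 CPM, Eomes at 518 against 3.78 CPM and Gzmk, a granzyme gene, at 921 against 29.4 CPM. A Cd4 UMI was found in 82 of its cells and a Cd8a UMI in 25, with 20 holding both, at a median of 8467 UMIs. In the remaining brain cells, 86.3% had a Cd4 UMI and 0.338% a Cd8a UMI. Of its 88 cells with a paired receptor, which fell into 50 clonotypes, 51 were in clonotypes of at least 2 cells.

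A receptor family chosen after it was seen, TRBV26 with TRBJ1-5 and TRAV7-5 with TRAJ32, held 65 brain cells (2.08%) in 2 clonotypes and 78 spleen cells (1.16%) in 3 clonotypes, with beta CDR3 sequences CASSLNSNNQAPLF, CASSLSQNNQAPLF and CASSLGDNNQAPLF. In clonotypes of at least 5 cells, the median share of cells in the leading class was 78.1% over 64 brain clonotypes and 80% over 23 spleen clonotypes. The mean length of the beta CDR3 was 13.9 amino acids in both tissues.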
